A study of Homo sapiens with 12 samples.

How the data were processed

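Total RNA from OVCAR-3 cells, a human high-grade serous ovarian carcinoma line, was collected 72 hours after transfection with small interfering RNA (siRNA) using Lipofectamine RNAiMAX. The 4 groups of 3 arrays received control siRNA, Oct4 siRNA (gene POU5F1), Ccnf siRNA together with Nipp1 siRNA (genes CCNF and PPP1R8), or Rb1 siRNA. They are called control, siOct4, siCcnf+siNipp1 and siRb1. Biotin-labelled RNA was hybridised to Illumina HT-12 bead arrays and detected with Cy3-streptavidin. Per the submitters' processing notes the arrays were read in GenomeStudio, whose version is not given in the sources used here. Sequences and amounts of the siRNAs are likewise not given in the sources used here. The labels call the samples biological replicates without saying that they were separate cultures, so every p-value measures a spread between samples that may be in part technical.

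The authors deposited a table with a signal intensity and a detection p-value for each of 47322 probes on each array, as the file headers name them. Tested on the values, the intensities were linear and not background-subtracted. The authors also deposited a normalized intensity for 47303 of the probes. These values had equal quantiles on all arrays and kept the rank order of the signals within each array, and the normalization method is not named. Array medians of the signal lay between 180.4 and 212. Between 16186 and 17351 probes per array, 34.2 to 36.7%, had a detection p-value under 0.01. The number of arrays limits the precision.

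The platform table pairs 30102 of the probes with exactly 1 gene and 8 with several. Of the 30102 gene identifiers, 30063 were found in the human reference gene table, which changed 0 symbols. The platform table names no gene for 17212 probes, and these probes entered no comparison of genes. No probe is paired with PPP1R8, so the transcript targeted by the Nipp1 siRNA could not be measured. The array files name no genome build, so coordinates are left out.

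Signals were corrected and normalized in R 4.3.3 with limma 3.58.1 by neqc, which models background from the detection p-values, adds an offset of 16, normalizes to equal quantiles and takes log2. Probes were kept with a detection p-value under 0.01 on at least 3 of the 12 arrays (14441 probes with 1 gene). Each gene was read by its kept probe with the highest mean, which gave 10873 genes out of 20039 with a probe. All 12 arrays entered 1 limma model with a mean per group (lmFit, eBayes; 8 residual and 3.85 prior degrees of freedom). The 6 comparisons between groups were contrasts of that model, all tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison. A gene was called changed at an adjusted p under 0.05. A moderated F test asked which genes differed among the 4 groups. Figures were drawn in Python 3.11.15.

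Where a probe was undetected on all 3 arrays of the lower group, or undetected on 1 or 2 of them with a fitted change of at least 2-fold, the change is given as a bound, "at least N-fold". It compares the mean of the higher group with the mean, over the lower group's arrays, of the larger of the array's lowest detected signal and the probe's own signal. The bound uses group means of values after neqc, so it is not a confidence limit. Other background handling, other arrays or another probe of the gene can give a smaller change. The largest changes were named by fitted values, so their order is not a ranking of bounds. Setting genes undetected on all 3 arrays at their bound moved a called list's median by at most 0.344 on the log2 scale (interferon response, siOct4) and changed the sign of 0 of 75 called medians.

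Choices made before the data were examined were the groups, the model, the filter, the thresholds, the alternatives, 33 gene lists (847 genes, 799 with a probe and 667 tested) and the rule for naming genes. Of the list genes, 23 stand in more than 1 list. Lists with at least 5 measured genes, 30 of the 33, were tested with camera at a preset inter-gene correlation of 0.01. The fibroblast, leukocyte and endothelial marker lists held 4, 3 and 3 measured genes and were not tested. With a correlation estimated from the arrays, camera called 0 lists in each of the 6 comparisons. At an unadjusted p under 0.05 it then gave 3, 3 and 3 lists for siOct4, siCcnf+siNipp1 and siRb1 against control, and 0, 2 and 3 for siOct4 against siCcnf+siNipp1, siOct4 against siRb1 and siCcnf+siNipp1 against siRb1. The directional test fry, which asks whether a list's genes move 1 way on balance and does not compare them with other genes, called 24, 24, 3, 9, 23 and 22 lists in the same order. Median, mean and camera direction differed in sign only for lists that camera did not call: against control, housekeeping genes with siOct4, the hypoxia and microRNA lists with siCcnf+siNipp1, and the chromosomal passenger, checkpoint, RB family, p53, unfolded protein and housekeeping lists with siRb1.

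The rule named the 4 targeted genes. It named the 10 largest rises and the 10 largest falls per comparison with control (5 for each pair of knockdowns) among called genes whose groups did not overlap. It also named up to 4 leading members of each called list, and the 5 leading genes per direction among those called in all 3 comparisons or in opposite directions. A further 10 genes were chosen here for the topics of the study's title, which does not name them. Genes without a symbol, or with a provisional LOC symbol, were counted only. List members that moved against their list, and others so marked, were named after their values were seen.

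Deviations from group means correlated between all arrays of the same replicate number (r across genes 0.107 to 0.419), and 12 of 12 arrays lay closest to an array of their own number, so the numbers pair the samples. The model without a replicate block had been fixed and was kept. Blocked values are given for the counts of called genes and for a few genes, and not for counts of list members. With the block 314 of 318 named gene results kept their side of the threshold and 4 gained a call. All 50 list results examined kept their side. Agreement between comparisons that share the 3 control arrays was set against 100 simulations without any effect, and after the pairing was seen against 100 more that kept each gene's replicate effects. Single targeted transcripts also had an exact permutation test of the 3 arrays against 3, two-sided, whose smallest possible p is 0.1.

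Alternatives tried were no background correction, the deposited normalized values, median scaling, no detection filter, detection on all 12 arrays, the mean of a gene's probes, only the 6 arrays compared, eBayes with trend and robust, a replicate block, arrayWeights, other thresholds, other list tests, and leaving out each array in turn. Leaving out the 4 arrays numbered 1 together was added after seeing the data. A slide block could not be fitted because the headers give no slide.

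The steps were tested on simulated data drawn with each gene's mean and residual spread over 10873 genes. Of 67 genes changed 1.5-fold, 30, 22 and 26 were called for siOct4, siCcnf+siNipp1 and siRb1 against control. At 2-fold it was 53, 46 and 60 of 67, and at 4-fold 66 of 66 in each. False calls were 8.06, 5.39 and 5.79% of the calls. All groups were drawn with the same spreads, so the values listed under each siRNA repeat the same setting and do not compare the knockdowns. The arrays were drawn without pairing. Far fewer genes changed than were called with siOct4 or siCcnf+siNipp1, so these shares need not hold there.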

Results

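Gene expression was measured in OVCAR-3 cells transfected with control siRNA or with siRNA against Oct4, against Ccnf and Nipp1 together, or against Rb1. The title of the series places these knockdowns in a study of OCT4, the mitotic spindle and the RB tumour suppressor pathway. OCT4, encoded by POU5F1, is a transcription factor of pluripotent cells. CCNF encodes cyclin F, a subunit of a ubiquitin ligase. NIPP1, encoded by PPP1R8, is a nuclear inhibitor of protein phosphatase 1. RB1 encodes the retinoblastoma protein, which restrains E2F transcription factors. Each of the 4 groups held 3 arrays, and each array had between 16186 and 17351 detected probes. Normalized values are on a log2 scale. Correlations across genes were 0.980 to 0.990 between arrays of a group (12 pairs) and 0.942 to 0.986 between arrays of different groups (54 pairs). The limma F test called 6331 of 10873 genes (58.2%) different among the 4 groups, and 7537 with a replicate block. The first principal component (39.6% of the variance) separated siOct4 and siCcnf+siNipp1 from control and siRb1, the second (27.7%) separated siOct4 from siCcnf+siNipp1, and the third (8.82%) separated siRb1 from control.

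The targeted transcripts were read first. POU5F1 had a normalized value of 10.58 ± 0.099 (SD, n = 3) in control. It was undetected on all 3 siOct4 arrays, at least 15.9-fold lower (adjusted p = 1.33e-07). CCNF fell from 11.91 ± 0.18 to 10.36 ± 0.54 with siCcnf+siNipp1, a log2 fold change of -1.55 ± 0.25 (SE; adjusted p = 0.000694), and was lower on 3 of 3 arrays than on every control array. RB1 had a control value of 7.76 ± 0.39 and was undetected on all 3 siRb1 arrays, at least 2.22-fold lower (adjusted p = 0.000772). The bounds for POU5F1 and RB1 rest on the background correction, and fitted falls were smaller without it. The exact permutation test gave p = 0.1 for each of these falls, the smallest value that 3 arrays against 3 allow. The Nipp1 target PPP1R8 could not be read, because no probe is named for it.

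Targeted genes also differed in the other knockdowns. CCNF changed by -0.96 ± 0.25 with siOct4 (SE, n = 3; adjusted p = 0.0124). Without siOct4 replicate 2 the log2 fold change was -0.85 and the adjusted p 0.0501, and over all alternatives it ranged from 0.00187 to 0.0501. CCNF did not pass with siRb1 (0.09, adjusted p = 0.905). RB1 changed by -0.61 with siOct4 (adjusted p = 0.0405), a call lost in 9 alternatives. Its adjusted p ranged from 0.00735 to 0.16 and was 0.105 without control replicate 1, 0.16 without control replicate 3, 0.153 without siOct4 replicate 2 and 0.0824 without siOct4 replicate 3. RB1 did not pass with siCcnf+siNipp1 (0.37, adjusted p = 0.181). POU5F1 rose by 1.03 with siCcnf+siNipp1 (adjusted p = 0.00267). That call was lost with the mean of its detected probes (0.27, adjusted p = 0.168; range over alternatives 5.87e-05 to 0.168). With siRb1 its log2 fold change was 0.80 (adjusted p = 0.0524, and 0.0359 with a replicate block; range over alternatives 0.00359 to 0.328). The second POU5F1 probe, paired with a different reference transcript, was 7.57 ± 0.24 with siOct4 and 7.30 ± 0.38 in control (log2 difference 0.27, 95% interval -0.16 to 0.71). With siCcnf+siNipp1, where the main probe rose, its log2 difference was -0.48 (limma unadjusted p = 0.0325, exact permutation p = 0.2), and with siRb1 it was -0.22 (limma unadjusted p = 0.293, exact permutation p = 0.7).

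**Figure D1:**
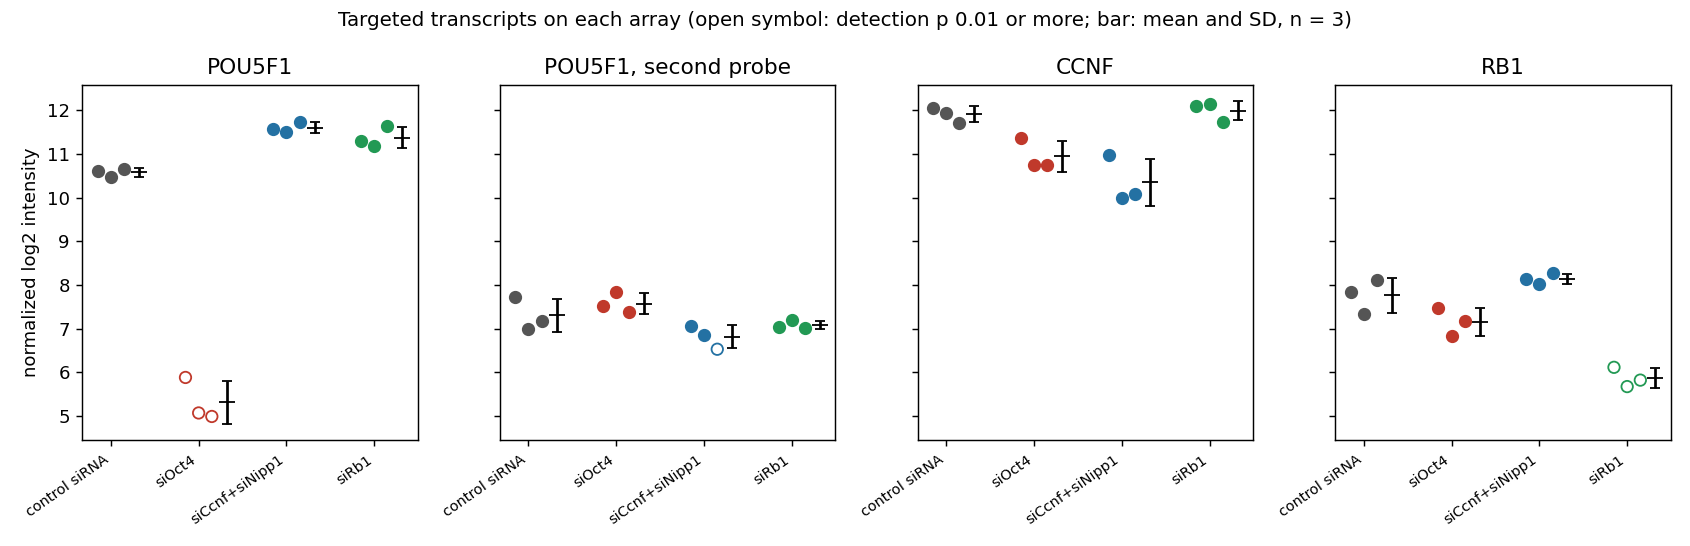
Normalized log2 intensity on each of the 12 arrays for the main POU5F1 probe, the second POU5F1 probe, CCNF and RB1, in the 4 groups; open symbols mark a detection p-value of 0.01 or more, and bars show the mean and SD of 3 arrays. POU5F1 falls from 10.58 to undetected values with siOct4, CCNF from 11.91 to 10.36 with siCcnf+siNipp1, and RB1 from 7.76 to undetected values with siRb1.

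Silencing of Oct4 was compared with control to ask which transcripts depend on OCT4 in these cells. At the preset correlation camera called lists of G2/M genes (29 of 33 lower), DNA replication (23 of 37) and homologous recombination (13 of 18) lower, and lists of interferon response (21 of 29 higher), NF-kB (9 of 13) and histone genes (8 of 17) higher. With an estimated correlation it called 0 of the 16 lists (3 at an unadjusted p under 0.05; adjusted p from 0.23 to 0.443). Beside POU5F1 itself, large falls included NTS, which encodes the secreted peptide neurotensin (at least 24.9-fold lower, adjusted p = 1.04e-05), OLR1, a scavenger receptor for oxidised lipoprotein (at least 17.8-fold, adjusted p = 9.4e-07), and PLEKHH2 (at least 4.74-fold, adjusted p = 7.18e-07). On the siOct4 arrays NTS was detected on 2 of 3 and OLR1 on 1 of 3. CDH1, which encodes the epithelial adhesion protein E-cadherin, went from 10.54 ± 0.15 to 7.44 ± 0.12 (SD, n = 3; adjusted p = 8.15e-06). CDC25C, a phosphatase that activates CDK1, was at least 3.09-fold lower, KRT25 at least 4.18-fold and the kinase gene PIM1 at least 4.26-fold. LMBRD2 changed by -2.71, and the cation transporter gene SLC22A2, detected on 2 of 3 siOct4 arrays, was at least 6.27-fold lower.

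TNF, an inflammatory cytokine, rose with siOct4 from 7.18 ± 0.55 to 11.44 ± 0.32 (SD, n = 3; adjusted p = 2.28e-06). IL32, another cytokine, was at least 11.4-fold higher (adjusted p = 2.17e-05), and its other probe rose by 3.06 on the log2 scale. SLPI, an inhibitor of serine proteases detected on 1 of 3 control arrays, was at least 14.5-fold higher (adjusted p = 0.00011, and 24.1-fold without siOct4 replicate 1). PI3, another such inhibitor, rose by 3.88 (adjusted p = 0.000188), with an SD of 1.22 among the siOct4 arrays. FLG, which encodes the epidermal barrier protein filaggrin, rose by 3.98 ± 0.19 (adjusted p = 6.2e-07) and the sphingosine-phosphate phosphatase gene SGPP2 by 4.05 (adjusted p = 2.28e-06). FAM107A had the largest fitted rise, 4.58 ± 0.92 (adjusted p = 0.00267), with an SD of 1.36 among the control arrays. HBE1, an embryonic globin gene, was at least 5.46-fold higher (10.1-fold without siOct4 replicate 1), PPP1R1A, an inhibitor of protein phosphatase 1, at least 5.26-fold, and the adhesion gene CEACAM1 at least 4.31-fold. The rule that named the largest changes took only genes whose 3 knockdown arrays lay on 1 side of the 3 control arrays.

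Lists of mitotic genes fell with siOct4. Of 12 measured genes of the chromosomal passenger complex and centromere cohesion, which correct chromosome attachment, 11 fell and 0 rose (median log2 fold change -1.33). Among them were AURKB (-1.34, adjusted p = 0.000394), BIRC5 (-1.46), CDCA8 (-1.33), SGO1 (-1.47) and SGO2 (at least 2.50-fold lower). INCENP, the scaffold of the complex, changed by -0.57 (adjusted p = 0.0179), a call lost without siOct4 replicate 2 (0.0748), control replicate 3 (0.0665) or siOct4 replicate 3 (0.0547), with a range over alternatives of 0.00293 to 0.0748. Of 30 kinetochore and centromere genes 24 fell, including CENPU (at least 4.66-fold), SPC25 (at least 3.71-fold) and NUF2 (at least 3.16-fold). Of 31 spindle motors and regulators 26 fell, with KIF4A at -1.67 and KIF2C at -1.56. Among 33 genes of the G2/M list 29 fell, including NCAPG (-1.86), CDK1 (-1.33), CCNB1 (-0.76, or -0.50 without siOct4 replicate 2) and MKI67 (at least 2.32-fold lower). In the spindle checkpoint list 13 of 26 fell, including CDC20 (-1.34) and BUB1B (-1.20), and ANAPC1 rose by 0.71. In the centrosome list 11 of 22 fell, with NEK2 at -1.49 and PLK4, the kinase of centriole duplication, at -1.42. Camera gave adjusted p = 1.02e-07, 1.62e-10, 3.79e-11, 8.41e-13, 5.8e-05 and 0.000173 for these lists in the order given. With an estimated correlation the adjusted p was 0.23, or 0.264 for the motor and centrosome lists. Adjusted over the list alone, 11, 24, 28, 30, 16 and 12 members fell.

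Genes of S phase fell as well. Of 40 E2F-driven G1/S genes 33 fell and 0 rose (median -0.997), with CHAF1B at -1.96, SKP2 at -1.53, RBL1 at least 2.52-fold lower and CCNE1, which encodes cyclin E1, at -0.76 (adjusted p = 0.00648). E2F1 itself did not pass (0.02, adjusted p = 0.977). Of 37 replication genes 23 fell, including GINS2 (-1.84), MCM10 (-1.45) and MCM2 (-0.70). Of 18 homologous recombination and Fanconi anaemia genes 13 fell, among them EME1 (at least 2.59-fold lower) and EXO1 (-1.46). Camera gave adjusted p = 1.59e-12, 3.57e-09 and 1.26e-05, and 0.23, 0.242 and 0.23 with an estimated correlation. Adjusted over the list alone, 34, 26 and 13 members fell. CDKN1A, the CDK inhibitor p21, rose by 0.56 (adjusted p = 0.00374), while the p53 target list did not pass (adjusted p = 0.169). The rise was read by 1 of 2 CDKN1A probes, and the other changed by 0.05.

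Interferon and inflammatory genes rose with siOct4. Of 29 interferon response genes 21 rose and 0 fell (22 adjusted over the list alone; median 1.20, or 0.85 with undetected genes at their bound). IFIT2 was at least 9.53-fold higher (adjusted p = 4.5e-05), and IFI44, OASL and IFIH1, a sensor of double-stranded RNA, were at least 2.36-, 2.18- and 2.08-fold higher. Of 13 NF-kB and cytokine genes 9 rose and 0 fell (10 adjusted over the list alone), with TNF in the lead and CXCL8 at 2.64, TNFAIP3 at 2.42 and RELB at least 4.39-fold higher. Camera gave adjusted p = 6.02e-09 and 4.02e-06, and 0.23 for both with an estimated correlation. Of 17 histone genes 8 rose, led by H2BC5 (2.20) and followed by H4C8 and H2AC6 (1.96), and H4C3 fell (-1.12). In the unfolded protein and amino acid stress list 10 of 26 rose, with SLC7A11, a cystine transporter, at 1.94 and ASNS, asparagine synthetase, at 1.65, while the chaperone gene HSP90B1 fell (-0.35). The adjusted p was 0.00258 and 0.00602, and 0.443 and 0.321 with an estimated correlation. Adjusted over the list alone the counts were 8 and 12 higher and 1 lower in each.

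Smaller falls with siOct4 were seen in RNA and energy metabolism. Of 27 spliceosome genes 11 fell, including SF3A3 (-0.76) and CDC5L (-0.64), and of 25 ribosome biogenesis genes 10 fell, including RRP9 (-1.34) and BOP1 (-0.64). Of 32 oxidative phosphorylation genes 6 fell, including SDHD (-0.81) and NDUFS3 (-0.40). That count is near the share of all genes called lower, 1807 of 10873. The camera adjusted p was 9.38e-05, 0.00196 and 0.0163, and 0.23, 0.264 and 0.27 with an estimated correlation; the last list did not pass without siOct4 replicate 2 (0.0723; range over alternatives 0.00293 to 0.0723). Adjusted over the list alone, 12, 11 and 4 members fell. The pluripotency list did not pass (adjusted p = 0.0764). In it LIN28A was at least 2.38-fold lower, DNMT3B and ALDH1A1 changed by -1.29 and -0.77, PROM1 rose by 1.96 and SOX2 was at least 1.81-fold higher, genes chosen after their values were seen. The epithelial list (0.596), mesenchymal (0.169), apoptosis (0.085), autophagy (0.154), cholesterol (0.545), hypoxia (0.59), cytosolic ribosomal protein (0.284), RB family (0.243), protein phosphatase 1 (0.601), WNT-Notch-Hedgehog (0.61), microRNA machinery (0.774) and housekeeping (0.697) lists did not pass either, adjusted p in parentheses.

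In total 3717 of 10873 genes (34.2%) passed the limma test for siOct4 against control, 1910 higher and 1807 lower, and 941 of them by at least 2-fold. Median scaling gave 1629 higher and 1657 lower. With a replicate block the count was 4753. Groups did not overlap for 46.1% of genes, where chance gives 10%. Camera called 16 of 30 lists, 4 higher and 12 lower, and 0 with an estimated correlation (3 at an unadjusted p under 0.05; fry called 24). Another split of the 6 arrays gave 19 lists.

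Cells with siCcnf+siNipp1 were compared with control to ask what changes with siRNA against these 2 transcripts. At the preset correlation camera called lists of G2/M genes (30 of 33 lower) and DNA replication (28 of 37) lower, and lists of autophagy (16 of 23 higher), interferon response (14 of 29) and mesenchymal genes (8 of 14) higher. With an estimated correlation it called 0 of the 19 lists (3 at an unadjusted p under 0.05; adjusted p from 0.225 to 0.399). ACTA2, which encodes smooth muscle actin, rose by 3.30 ± 0.18 (SE, adjusted p = 1.73e-06) and LCP1, the actin-bundling L-plastin, by 3.02 (adjusted p = 1.9e-05). The kinase gene RPS6KA2 was at least 7.82-fold higher, AKR1C3, an aldo-keto reductase of steroid and prostaglandin metabolism, at least 6.06-fold, CEACAM1 at least 4.98-fold (7.77-fold without siCcnf+siNipp1 replicate 1) and the protocadherin gene PCDH7 at least 3.29-fold. PANX2 rose by 2.81 and SHISA2 by 3.26 (SD 1.03 in control). MR1, which presents vitamin B metabolites to T cells, rose by 2.75 (adjusted p = 3.56e-06), and the butyrophilin gene BTN3A2 was at least 3.20-fold higher. Another BTN3A2 probe rose by 1.385 on the log2 scale.

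Large falls with siCcnf+siNipp1 included CCNA1, which encodes cyclin A1 (-3.69 ± 0.28, SE, adjusted p = 8.09e-06), and FBLN2, the matrix protein fibulin 2 (at least 12.6-fold lower, adjusted p = 3.59e-07; detected on 2 of 3 siCcnf+siNipp1 arrays). MSLN, which encodes the ovarian carcinoma antigen mesothelin, was at least 3.02-fold lower (adjusted p = 1.73e-06), KIF1A at least 4.08-fold and IL1RN, the interleukin 1 receptor antagonist, at least 2.37-fold. CDH1 changed by -2.64 ± 0.24 (adjusted p = 1.9e-05), and the neuropeptide gene NMU by -2.71. ALPL, an alkaline phosphatase detected on 1 of 3 siCcnf+siNipp1 arrays, was at least 3.89-fold lower, and TERC, the telomerase RNA, detected on 2 of 3, at least 5.81-fold.

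Cell-cycle lists fell with siCcnf+siNipp1 too, and none of them passed the camera test between siOct4 and siCcnf+siNipp1. In the chromosomal passenger list 11 of 12 genes fell (median -1.06), including AURKB (-1.54), CDCA8 (-1.46), BIRC5 (-1.23) and INCENP (-0.79, adjusted p = 0.00283). Of 30 kinetochore genes 27 fell, with CENPF at -1.82 and CENPU at -1.65, and of 31 spindle motors and regulators 28 fell, with HMMR at -1.72 and KIF15 at -1.70. Among 33 G2/M genes 30 fell, including CCNB1 (-1.37), CDK1 (-0.98) and NCAPG (-1.46). In the spindle checkpoint list 16 of 26 fell, led by ESPL1, the cohesin protease separase (-1.77), and ANAPC1 (0.50) and ANAPC13 (0.53) rose. In the centrosome list 12 of 22 fell, including NEK2 (-1.05), and NDEL1 rose (0.52). Of 40 E2F-driven genes 36 fell, including MYB (at least 3.78-fold lower), RRM2 (-1.84) and LIG1 (-1.51), of 37 replication genes 28 fell, including WDHD1 (at least 3.38-fold lower) and MCM2 (-1.05), and of 18 recombination genes 14 fell, including RAD54L (-1.70). Camera gave adjusted p = 4.39e-06, 2.16e-10, 7.66e-11, 7.66e-11, 0.000248, 0.00336, 8.9e-13, 2.86e-11 and 2.54e-06 in this order, and 0.225 for each with an estimated correlation except the centrosome list (0.348). Adjusted over the list alone, 11, 29, 28, 31, 16, 13, 36, 29 and 14 members fell. CCNE1 changed by -0.64 (adjusted p = 0.0142), a call lost without control replicate 1 (0.0506) or siCcnf+siNipp1 replicate 3 (0.0629) and with the mean of its probes (0.0682), in a range of 0.000941 to 0.0682. E2F1 did not pass (-0.52, adjusted p = 0.284).

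Autophagy and lysosome genes rose with siCcnf+siNipp1, 16 of 23 and 0 lower (16 adjusted over the list alone; median 0.55). WIPI1 was at least 3.54-fold higher, MAP1LC3B, the LC3B protein of the autophagosome membrane, rose by 1.55 and GABARAPL1 by 1.48. Of 14 mesenchymal and TGF-beta genes 8 rose (8 adjusted over the list alone), with ACTA2 followed by the integrin genes ITGB3 (at least 3.32-fold higher) and ITGA5 (1.71). Of 26 genes of the unfolded protein and amino acid stress list 9 rose (9 adjusted over the list alone), including VLDLR (1.39) and DNAJC3 (1.10). In the interferon list 14 of 29 rose and 2 fell (14 and 2 adjusted over the list alone; median 0.55, or 0.46 with undetected genes at their bound), with IFIT2 at least 5.17-fold higher, IFI35 at 1.54, and BST2 (-0.33) and XAF1 (-0.62) lower. Camera gave adjusted p = 6.43e-06, 0.000419, 0.00114 and 0.000193, and 0.225 for each with an estimated correlation.

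In the p53 target list 8 of 22 genes rose and 1 fell with siCcnf+siNipp1 (8 and 1 adjusted over the list alone). The death receptor gene FAS was at least 2.47-fold higher, TNFRSF10B rose by 1.26 and CDKN1A by 0.90 (adjusted p = 0.000203), and the repair gene XPC fell (-0.53). The other of the 2 CDKN1A probes changed by 0.02. The NF-kB list rose in 5 of 13 genes (5 adjusted over the list alone), TNF by 2.52, RELB at least 2.85-fold, TNFAIP3 by 0.78, NFKBIA by 0.65 and SOD2 by 0.49. The TNFAIP3 call (adjusted p = 0.0342; range 0.00289 to 0.0987) was lost without control replicate 1 (0.0563), 2 (0.0889) or 3 (0.0811), or siCcnf+siNipp1 replicate 2 (0.0987) or 3 (0.0784). The NFKBIA call (adjusted p = 0.0211; range 0.00728 to 0.0842) was lost without control replicate 2 (0.0689) or 3 (0.0816), or siCcnf+siNipp1 replicate 1 (0.0507) or 2 (0.0842). The epithelial and serous carcinoma list fell in 6 of 19 genes (6 adjusted over the list alone), with MSLN, CDH1 and KRT8 in the lead. For these 3 lists camera gave adjusted p = 0.0231, 0.0307 and 0.0109, and 0.225, 0.399 and 0.225 with an estimated correlation. None of the 3 passed when detection on all 12 arrays was required (0.0728, 0.0952 and 0.0837), nor did the p53 list without control replicate 2 (0.0537) and the NF-kB list without siCcnf+siNipp1 replicate 2 (0.0641). Over all alternatives their adjusted p ranged from 0.0071 to 0.0728, 0.0102 to 0.0952 and 0.00394 to 0.0837.

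Ribosome biogenesis genes fell in 14 of 25 with siCcnf+siNipp1 (17 adjusted over the list alone), including RRP9 (-1.14) and DKC1, the dyskerin of telomerase and small nucleolar particles (-0.95). Spliceosome genes fell in 9 of 27 (9 adjusted over the list alone), including SRSF7 (-0.85), and oxidative phosphorylation genes in 6 of 32 (6 adjusted over the list alone), including COX5B (-0.58). The count for oxidative phosphorylation is near the share of all genes called lower, 2102 of 10873. The camera adjusted p was 6.43e-06, 0.000118 and 0.00158, and 0.225 for each with an estimated correlation. Lists that did not pass were histones (adjusted p = 0.0594), apoptosis (0.0655), cholesterol (0.1), cytosolic ribosomal proteins (0.305), housekeeping (0.344), pluripotency (0.572), WNT-Notch-Hedgehog (0.584), protein phosphatase 1 (0.814), hypoxia (0.83), microRNA machinery (0.83) and the RB family (0.848).

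The limma test called 4168 of 10873 genes (38.3%) for siCcnf+siNipp1 against control, 2066 higher and 2102 lower, with 1025 changed at least 2-fold. Median scaling moved the share of calls that were higher from 49.6 to 42.1% (1560 higher and 2144 lower). A replicate block gave 5230. Groups did not overlap for 51.1% of genes. Camera called 19 lists, 6 higher and 13 lower, and 0 with an estimated correlation (3 at an unadjusted p under 0.05; fry called 24). Another split of the 6 arrays gave 21 lists.

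Silencing of Rb1 was compared with control to ask what changes with siRNA against the retinoblastoma transcript, and fewer genes passed than in the other knockdowns. PAPPA, a protease that releases insulin-like growth factor, was at least 3.21-fold higher (adjusted p = 0.000851), and the transcription factor gene IRX3 and the growth factor gene MDK (midkine) rose by 2.04 ± 0.25 and 1.96 ± 0.23 (SE, adjusted p = 0.00102 and 0.000909). VTCN1, an inhibitory ligand of T cells, rose by 1.91 and TMSB15A by 1.86. The protease genes ADAM19 and HTRA1, each detected on 2 of 3 control arrays, were at least 3.44- and 3.49-fold higher. SLAIN1, which encodes a microtubule-binding protein, was at least 2.09-fold higher. Another probe gave smaller log2 fold changes for SLAIN1 (0.66) and MDK (1.09). Beside RB1 itself, LIN28A, an RNA-binding protein of stem cells, was at least 2.35-fold lower (adjusted p = 0.00031), IL1RN at least 2.44-fold and the keratin gene KRT8 at least 2.06-fold. CDH1 changed by -1.58 ± 0.24 (adjusted p = 0.00395), the amino acid transporter gene SLC7A8 by -1.60 and GPX2, a glutathione peroxidase, by -1.87. ZNF467 rose by 1.97 (adjusted p = 0.0106; range over alternatives 0.00188 to 0.0787, the highest without the 4 arrays numbered 1).

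The calls of 4 of the largest changes with siRb1 were lost when 1 array was left out, while their fitted log2 fold changes kept their direction. IFIT2, detected on 1 of 3 control arrays, was at least 3.18-fold higher (adjusted p = 0.0143; range 0.00305 to 0.0661), a call lost without control replicate 2 (0.0522) or siRb1 replicate 3 (0.0661), where the log2 fold change went from 1.72 to 1.62 and 1.53. FAM181B was at least 1.46-fold lower (adjusted p = 0.013; range 0.00332 to 0.0635), which was lost without control replicate 3 (0.0635) or siRb1 replicate 3 (0.0622), where its fitted log2 fold change went from -1.61 to -1.55 and -1.43. SNAR-A1, a small noncoding RNA, changed by -2.16 (adjusted p = 0.0353; range 0.00402 to 0.135). It did not pass without control replicate 1 (0.0854), 2 (0.0977) or 3 (0.106), or siRb1 replicate 2 (0.106) or 3 (0.135), with log2 fold changes from -2.22 to -1.73, nor without the detection filter (0.0529). The secretoglobin gene SCGB2A1 was at least 2.51-fold lower (adjusted p = 0.0224; range 0.00612 to 0.0952), lost without control replicate 2 (0.0824) or 3 (0.0952), or siRb1 replicate 1 (0.0598), 2 (0.0848) or 3 (0.0585), with log2 fold changes from -2.13 to -1.80.

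The cell-cycle lists did not pass with siRb1, with or without a replicate block. The block raised all siRb1 calls from 511 to 1162, and the counts of members given here are without it. Limma called 0 of 40 E2F-driven genes (1 higher and 1 lower at an unadjusted p under 0.05; median 0.02, camera adjusted p = 0.889) and 0 of 33 G2/M genes (0 and 0 unadjusted; median -0.04, adjusted p = 0.889). It called 0 of 31 spindle motors (0 and 0), 0 of 30 kinetochore genes (1 and 1), 0 of 26 checkpoint genes (3 higher and 1 lower), 0 of 22 centrosome genes (3 and 2), 0 of 37 replication genes (0 and 0) and 0 of 18 recombination genes (0 and 0), with unadjusted counts in parentheses and camera adjusted p from 0.28 to 0.968. In the chromosomal passenger list 1 of 12 genes fell, RCC2 (-0.60, adjusted p = 0.0123), chosen after its value was seen. None of the 10 genes chosen here for the topics of the study's title passed with siRb1: E2F1 had a log2 fold change of -0.23 (adjusted p = 0.803), CCNE1 of 0.01 (0.981), MCM2 of -0.06 (0.879), CCNB1 of 0.19 (0.706), CDK1 of 0.04 (0.954), CDKN1A of 0.09 (0.759), AURKB of -0.17 (0.722), BIRC5 of 0.22 (0.649), CDCA8 of -0.28 (0.459) and INCENP of 0.07 (0.863).

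Interferon response genes rose with siRb1 as a list (median 0.39, camera adjusted p = 1.65e-05; adjusted p = 0.435 with an estimated correlation). Of 29 genes 4 rose and 0 fell (5 adjusted over the list alone), namely IFIT2, OAS3 (at least 2.08-fold higher), IFIT1 (1.11) and BST2 (0.56). The IFIT1 and BST2 calls were lost without control replicate 3 (0.0603 and 0.0606) or siRb1 replicate 3 (0.053 and 0.0585), in ranges of 0.00213 to 0.0603 and 0.00282 to 0.0893, and the upper end for BST2 came with median scaling. Epithelial genes fell in 5 of 19 (7 adjusted over the list alone), namely KRT8, CDH1, OVOL2 (-1.05), KRT18 (-0.59) and SPINT2 (-0.54), with camera adjusted p = 0.000736 (0.424 with an estimated correlation). OVOL2 did not pass without control replicate 3 (0.0558; range 0.00275 to 0.0558). KRT18 did not pass without control replicate 1 (0.0951), 2 (0.0647) or 3 (0.101), or siRb1 replicate 2 (0.0919) or 3 (0.119), with a range of 0.0105 to 0.124. The call of SPINT2, outside the naming rule, was not put through the alternatives.

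Further lists were lower with siRb1 by the camera test while few of their members passed. Histones had a median of -0.64 (adjusted p = 0.00057; 0.72 with an estimated correlation) and oxidative phosphorylation of -0.14 (0.000652; 0.424 with an estimated correlation). Cholesterol biosynthesis had a median of -0.21 (0.00774; 0.435 with an estimated correlation) and ribosome biogenesis of -0.14 (0.0102; 0.683 with an estimated correlation). Limma called 1 of 17 histone genes (1 adjusted over the list alone), H2AC18 (-0.94, adjusted p = 0.03; range 0.00921 to 0.119). It lost its call without control replicate 1 (0.0724), 2 (0.0698) or 3 (0.119), or siRb1 replicate 1 (0.0929) or 2 (0.109). In the cholesterol list 1 of 17 genes passed (5 lower adjusted over the list alone), MVD (-0.67, adjusted p = 0.0457; range 0.0144 to 0.167). Its call was lost without any 1 of the 6 arrays, from 0.0648 without siRb1 replicate 2 to 0.167 without siRb1 replicate 3. For oxidative phosphorylation limma called 0 of 32 genes (0 higher and 6 lower at an unadjusted p under 0.05; 0 adjusted over the list alone), with NDUFV1 at -0.43 (adjusted p = 0.122; 0.0166 with a replicate block). For ribosome biogenesis it called 0 of 25 (1 higher and 5 lower unadjusted; 0 adjusted over the list alone), with RRP9 at -0.52 (adjusted p = 0.0977; 0.0247 with a replicate block). The other lists did not pass: pluripotency (adjusted p = 0.0533), hypoxia (0.0719), mesenchymal (0.45), autophagy (0.5), WNT-Notch-Hedgehog (0.5), p53 targets (0.707), NF-kB (0.775), protein phosphatase 1 (0.889), microRNA machinery (0.889), housekeeping (0.889), spliceosome (0.931), apoptosis (0.951), cytosolic ribosomal proteins (0.951), the unfolded protein response (0.961) and the RB family (0.961).

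For siRb1 against control the limma test called 511 of 10873 genes (4.70%), 322 higher and 189 lower, and 148 at least 2-fold. Groups did not overlap for 27.3% of genes. The replicate block gave 1162 calls and arrayWeights 1035, while single arrays left out gave 165 (control replicate 3), 227 (siRb1 replicate 3), 271 (siRb1 replicate 2), 310 (siRb1 replicate 1), 320 (control replicate 2) and 347 (control replicate 1). The share of calls that were higher, 63.0%, became 39.8% under median scaling (162 higher and 245 lower).

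**Figure D2:**
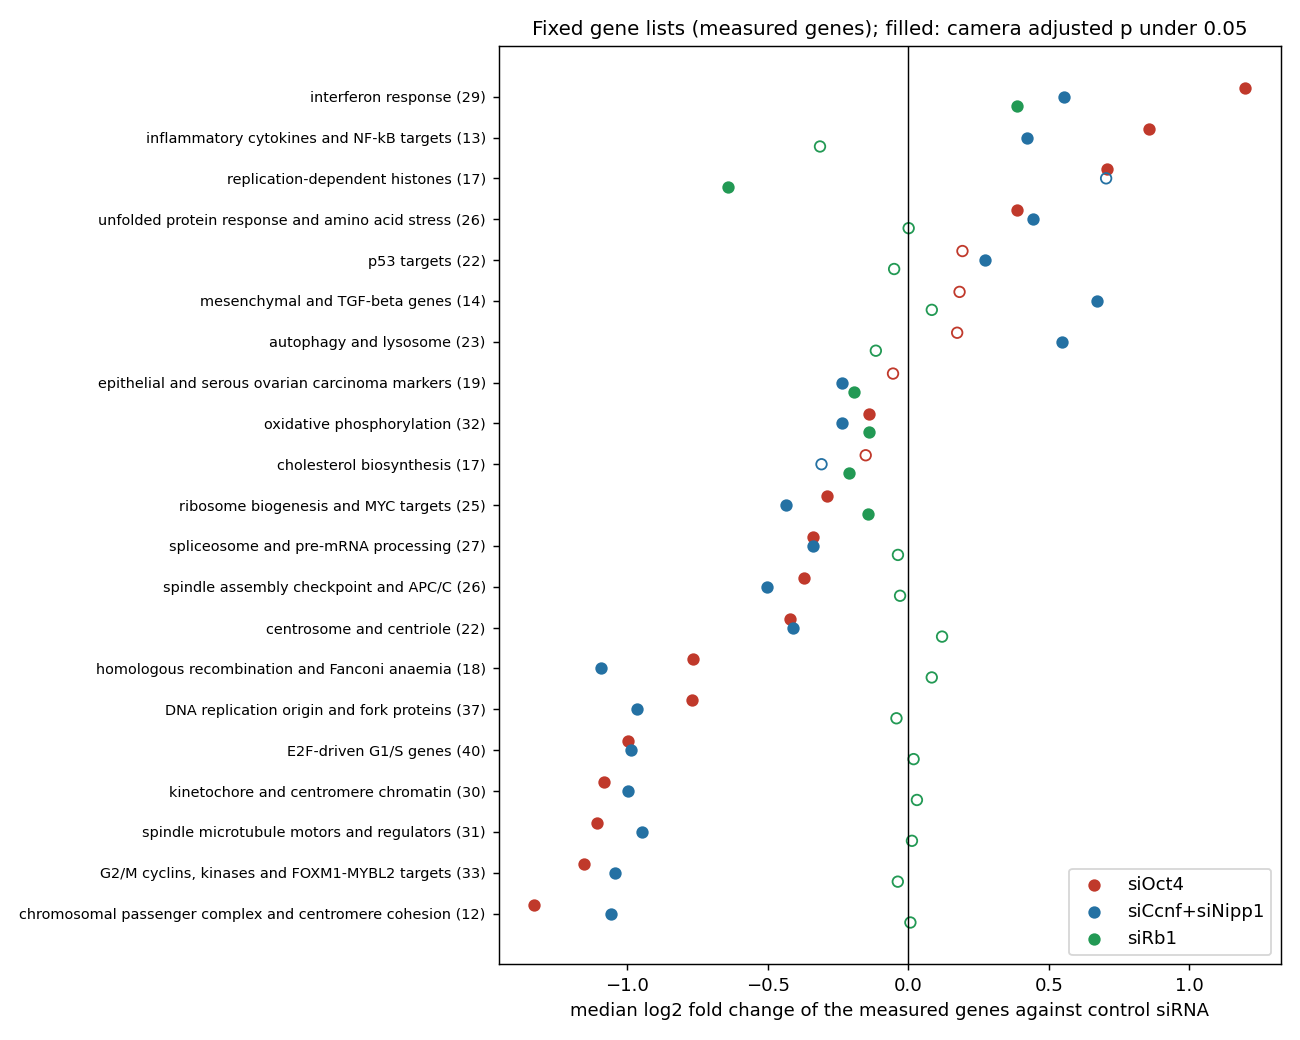
Median log2 fold change against control of the measured genes of 21 lists, each called in at least 1 comparison, for siOct4 (red), siCcnf+siNipp1 (blue) and siRb1 (green); filled symbols mark a camera adjusted p under 0.05 at the preset correlation. The G2/M list has medians of -1.16 with siOct4, -1.04 with siCcnf+siNipp1 and -0.04 with siRb1, and the interferon list of 1.20, 0.55 and 0.39.

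The knockdowns were then set against each other, which tests the differences directly. Between siOct4 and siCcnf+siNipp1, POU5F1 was at least 32.4-fold lower with siOct4. TMEM158 (-3.95), TNFRSF11B, the decoy receptor osteoprotegerin (-3.44), LIFR (at least 6.41-fold) and CA5B (at least 5.67-fold) were also lower with siOct4, while FAM107A (at least 39.4-fold), FBLN2 (at least 14.6-fold), PI3 (3.79), SCARNA8 (at least 12.4-fold) and FAM25A (3.13) were higher. On the siCcnf+siNipp1 arrays FAM107A was detected on 1 of 3 (replicate 1), and FBLN2 and SCARNA8 on 2 of 3. The FAM107A bound was 88.4-fold without siCcnf+siNipp1 replicate 1 and 25.8-fold without replicate 2, so 39.4-fold is not a minimum. Its fitted log2 fold change was 5.56 ± 0.92 (SE), with an SD of 2.27 among the siCcnf+siNipp1 arrays. CCNF did not pass between them (0.59, adjusted p = 0.0888; 0.0191 with a replicate block and 0.00707 without siCcnf+siNipp1 replicate 1, in a range of 0.00707 to 0.282), and RB1 was lower with siOct4 (-0.99, adjusted p = 0.0036). Autophagy genes were lower with siOct4 in 10 of 23 (11 adjusted over the list alone), including GABARAPL1 (-1.89), HEXA (at least 2.04-fold lower) and ULK1 (-0.81), with camera adjusted p = 0.00339. NF-kB genes were higher in 7 of 13, including CXCL8 (2.02), TNF (1.74) and TNFAIP3 (1.64), with adjusted p = 0.006; these members were chosen after their values were seen. With an estimated correlation the adjusted p was 0.97 for both, and the other 28 lists did not pass. Another split of these 6 arrays gave 15 lists.

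Against siRb1, siOct4 cells had less POU5F1 (at least 27.6-fold), NTS (at least 14.6-fold), PLEKHH2 (at least 3.95-fold), OLR1 (at least 6.01-fold), TCF4 (at least 3.22-fold) and CCNF (-1.04, adjusted p = 0.00807), and more PI3 (at least 21.3-fold; detected on 1 of 3 siRb1 arrays), IL32 (at least 10.7-fold), SLPI (at least 13.7-fold), HBE1 (at least 5.13-fold) and LCP1 (4.05). Against siRb1, siCcnf+siNipp1 cells had more CRYAB, a small heat shock protein (at least 6.05-fold), LCP1 (3.63), AKR1C3 (at least 5.69-fold), CFAP58 (at least 4.43-fold) and CEACAM1 (at least 4.68-fold). They had less TMSB15A (at least 6.06-fold), FBLN2 (at least 13.1-fold), MSLN (at least 3.49-fold), ALPL (at least 4.99-fold), FAM107A (at least 14.96-fold; SD 2.27 with siCcnf+siNipp1) and CCNF (-1.64, adjusted p = 0.000553). Of these bounds, leaving out siOct4 replicate 1 moved PI3 to 34.4-fold, SLPI to 22.9-fold and HBE1 to 9.50-fold. Leaving out siCcnf+siNipp1 replicate 1 moved CRYAB to 12.1-fold, CEACAM1 to 7.30-fold and FAM107A to 33.5-fold, and leaving out siCcnf+siNipp1 replicate 2 moved FAM107A to 9.78-fold. RB1 was at least 1.45- and 2.88-fold higher in siOct4 and siCcnf+siNipp1 cells than in siRb1 cells. In the G2/M list 28 of 33 genes were lower with siOct4 than with siRb1 (adjusted p = 1e-12; 0.281 with an estimated correlation) and 29 were lower with siCcnf+siNipp1 (7.14e-11; 0.302 with an estimated correlation). Interferon genes were higher with siOct4 than with siRb1 in 16 of 29 (adjusted p = 0.000291; 0.295 with an estimated correlation).

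Limma called 3824 genes between siOct4 and siCcnf+siNipp1 (1949 higher and 1875 lower with siOct4; 4911 with a replicate block), 3630 between siOct4 and siRb1 (1803 higher and 1827 lower with siOct4; 4653 with the block) and 3915 between siCcnf+siNipp1 and siRb1 (1915 higher and 2000 lower with siCcnf+siNipp1; 4913 with the block). Camera called 2, 15 and 17 lists, and 0, 0 and 0 with an estimated correlation (0, 2 and 3 at an unadjusted p under 0.05; fry called 9, 23 and 22). Median scaling moved the share of higher calls between siOct4 and siRb1 from 49.7 to 61.1% (1955 higher and 1245 lower), between siOct4 and siCcnf+siNipp1 from 51.0 to 56.5% (1905 and 1467), and between siCcnf+siNipp1 and siRb1 from 48.9 to 54.3% (1810 and 1526).

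Agreement between knockdowns was counted against the shared controls. With siOct4 and siCcnf+siNipp1, 914 genes were called higher in both, 835 lower in both and 244 in opposite directions, where independent calls would give 362.9, 349.3 and 712.6. With siOct4 and siRb1 the counts were 186, 83 and 36 (56.56, 31.41 and 86.71 for independent calls), and with siCcnf+siNipp1 and siRb1 199, 83 and 38 (61.18, 36.54 and 98.16). The 3 control arrays enter every comparison, and simulations without any effect gave a covariance of log2 fold changes of 0.0211, 0.0212 and 0.0211 and a correlation across genes of 0.499, 0.501 and 0.499. The measured covariances were 0.191, 0.0596 and 0.0649, exceeding the simulated ones by 0.170, 0.0384 and 0.0438, and the measured correlations were 0.518, 0.296 and 0.320. These simulations ignore the pairing of the arrays. Simulations that kept each gene's replicate effects, chosen after the pairing was seen, gave a covariance of 0.0152 in each case, exceeded by the measured ones by 0.176, 0.0444 and 0.0497, and a correlation of 0.498, 0.5001 and 0.499. In the 100 simulations of each kind the highest count of calls in the same direction was 0. Few genes are called where none changes, so this count does not show how many shared calls the controls add. Same-direction calls with siRb1 fell when 1 array was left out: the 269 with siOct4 became 93 without control replicate 3, 176 without control replicate 2, and 169, 161 and 134 without siRb1 replicates 1, 2 and 3. The 282 with siCcnf+siNipp1 became 102 without control replicate 3, and 178, 162 and 139 without siRb1 replicates 1, 2 and 3. With a replicate block they were 598 and 623.

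Of the 511 genes called with siRb1, 412 were called in another comparison with control, where independent calls would give 276.9, since 5892 of 10873 genes (54.2%) were called with siOct4 or siCcnf+siNipp1. In all 3 comparisons 134 genes were higher and 50 lower (10.75 and 6.072 for independent calls). All of these counts share the control arrays, so part of the excess may come from them. Simulations of both kinds gave 0 at most, but a count near 0 is fixed in advance where no gene changes. They cannot show how much the shared arrays add where genes do change. The 412 became 135 of 165 calls without control replicate 3, 278 and 259 without control replicates 1 and 2, and 255, 225 and 190 without siRb1 replicates 1, 2 and 3. The 134 and 50 became 48 and 22 without control replicate 3, 89 and 33 without control replicate 2, 82 and 38 without siRb1 replicate 1, 76 and 36 without siRb1 replicate 2, and 71 and 26 without siRb1 replicate 3. With a replicate block the counts were 955 of 1162, 280 and 126. EBI3, a cytokine subunit, rose by 3.42, 2.51 and 1.67 with siOct4, siCcnf+siNipp1 and siRb1, and RPS6KA2 was at least 6.28-, 7.82- and 2.85-fold higher. CDH1 changed by -3.09, -2.64 and -1.58 and OLR1 was at least 17.8-fold lower with siOct4 and changed by -1.37 and -1.56 with the others, while LIN28A was at least 2.38-, 2.28- and 2.35-fold lower, and KRT8, lower in all 3, was at least 2.09-fold lower with siOct4 and 2.06-fold with siRb1. Among genes called in opposite directions, TMEM158 changed by -2.15 with siOct4 and 1.80 with siCcnf+siNipp1, and TNFRSF11B by -1.45 and 1.99. TCF4 was at least 1.02-fold lower with siOct4 and at least 3.12-fold higher with siRb1, and TMSB15A was at least 1.68-fold lower with siCcnf+siNipp1 and rose by 1.86 with siRb1.

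**Figure D3:**
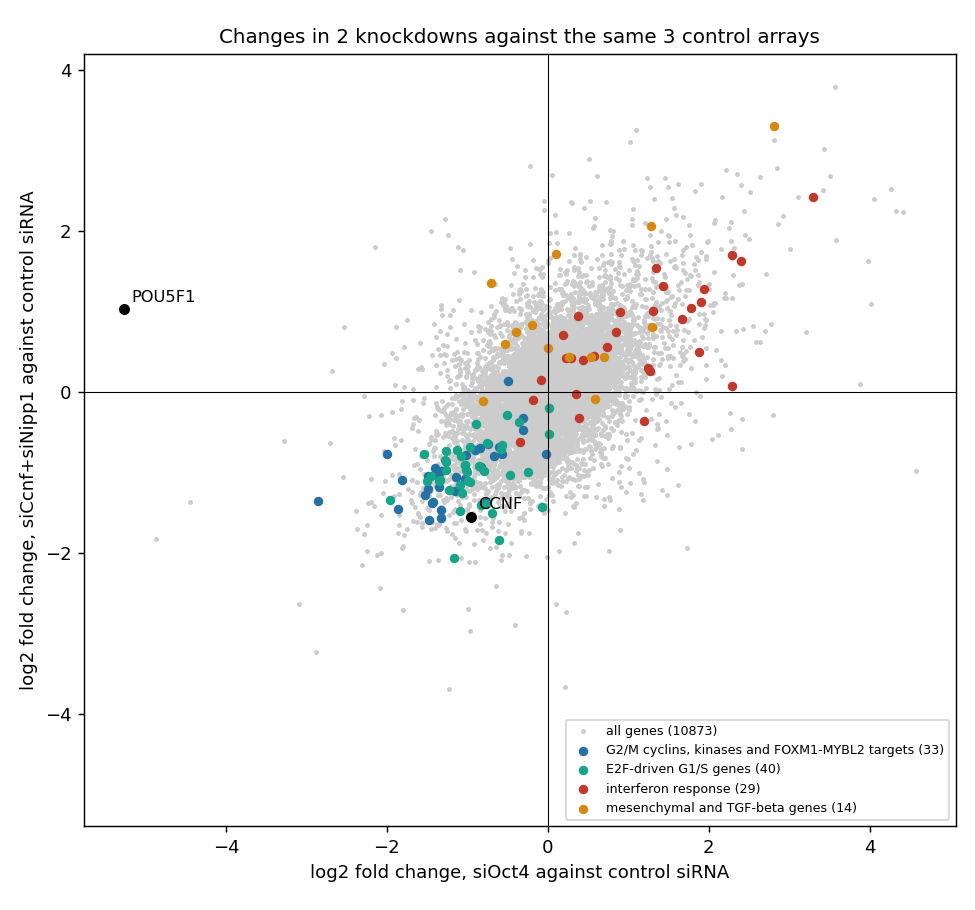
Log2 fold change against control with siOct4 (horizontal axis) and siCcnf+siNipp1 (vertical axis) for 10873 genes, 1 point each, with 33 G2/M, 40 E2F-driven, 29 interferon and 14 mesenchymal genes in colour and POU5F1 and CCNF labelled, POU5F1 at its fitted value although it is undetected with siOct4. Most G2/M and E2F-driven genes lie below 0 on both axes, and both axes share the 3 control arrays.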

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

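The tests on the second POU5F1 probe, on weaker knockdown in replicate 1, on the interferon genes and on splits within replicate numbers were chosen only after the results were seen.

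Probes without a gene in the platform table, a signal outside the comparisons of genes, changed as well. Of 3978 such probes tested, 772 were called with siOct4 (400 higher and 372 lower), 647 with siCcnf+siNipp1 (290 and 357) and 16 with siRb1 (6 and 10), each against control.

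The second POU5F1 probe did not fall with siOct4 while the main probe became undetected. It was detected on 11 of 12 arrays, which argues against background alone. The lower 95% limit of its log2 fold change was -0.16, which argues against both probes reading 1 transcript that fell as far as the main probe showed. The platform table pairs the probes with 2 different reference transcripts, so the second probe may read a transcript or locus that the siRNA left in place. That stays open, because no probe sequence or genome was used here, and no biological explanation was tested.

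Changes were weaker on the arrays numbered 1 of siOct4 and siCcnf+siNipp1, with slopes of 0.652 and 0.671 where the other replicates had 1.03 to 1.08. Each replicate was set against the mean of the 2 others, over genes changed at least 2-fold in that mean. For replicates 2 and 3 that mean includes the weaker replicate 1, which raises their slopes. Against the other 2 control arrays the higher of the slopes was still 0.742, which argues against a control array out of place as the whole cause. The slope of siRb1 replicate 1 was 0.674, so that all arrays numbered 1 may give compressed ratios; it rests on 226 genes with small changes, it was 0.855 against the other 2 controls, and siRb1 replicate 2 had 0.866. Weaker knockdown could also contribute: the log2 ratio of CCNF to the control of the same number was -1.08 in siCcnf+siNipp1 replicate 1 and -1.96 and -1.62 in replicates 2 and 3. For POU5F1 the ratio was -4.725 in siOct4 replicate 1 and -5.404 and -5.678 in replicates 2 and 3. Weaker knockdown stays open, because CCNF also follows the response to siOct4 and POU5F1 was undetected on all 3 siOct4 arrays. Leaving out the 4 arrays numbered 1 gave 3096, 3454 and 241 called genes for siOct4, siCcnf+siNipp1 and siRb1 against control.

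Camera at the preset correlation called the interferon response list higher than control in all 3 knockdowns (adjusted p = 0.23, 0.225 and 0.435 with an estimated correlation). For siOct4, low values on the control arrays alone are argued against, since the list was also higher than in siRb1 cells (median 0.50, camera adjusted p = 0.000291, or 0.295 with an estimated correlation). For siRb1 the median of 0.39 may come from the controls, because array means of the list were 8.40 to 8.45 in control and 8.84 to 8.92 with siRb1, and the control siRNA group is the only reference group. Differences in amount or sequence of the RNA duplexes could give the order of the groups (siOct4 against siCcnf+siNipp1: median 0.31, adjusted p = 0.068) and cannot be told apart from the knockdowns, since each group had its own siRNA and the labels give no amounts. An effect of the silenced genes themselves stays open and untested.

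Other splits of the 6 arrays of a comparison are too few, 10, for a share under 0.05. The real split gave 3717 genes for siOct4, 4168 for siCcnf+siNipp1 and 511 for siRb1 against control, where the highest other split gave 0, 0 and 1. Between knockdowns the real values were 3824, 3630 and 3915 and the highest others 0, 0 and 1 (siOct4 against siCcnf+siNipp1, siOct4 against siRb1, siCcnf+siNipp1 against siRb1). In each of these 6 comparisons 1 split, the real one, gave as many genes. For lists against control the real values were 16, 19 and 6 and the highest others 19, 21 and 4, and 3, 2 and 1 of the 10 splits gave as many. Between knockdowns, in the order above, the real splits called 2, 15 and 17 lists and the highest others 15, 18 and 20. Of 100 drawn splits of all 12 arrays into 4 groups, 1, the real one, gave as many as 6331 genes, and the highest other gave 1524. For the F test a random split is thus unlikely to give as many, if arrays are exchangeable. Because the numbers pair the arrays, 100 splits with 1 array of each number in every group were drawn as well. Of these 1, the real one, gave as many genes, and the highest other gave 4688, so as many are unlikely from a random split with the pairing kept. A share of 1 in 100 is the smallest that these draws can give. They cannot speak on chance between cultures, since the labels do not say that the samples were separate cultures. The splits that part all 3 numbered pairs gave up to 17 lists with siOct4, 21 with siCcnf+siNipp1 and 1 with siRb1, and those parting 1 pair up to 19, 18 and 4.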

How the results depend on the processing

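Leaving out the 4 arrays numbered 1 was chosen after seeing the data. Of 5261 alternative values of 318 named gene results, 5046 kept their side of the threshold, 201 lost the call, 14 gained it and 0 called values reversed. Of the 5046, 21 changed sign without a call on either side. Of 850 alternative values of 50 list results, 844 kept their side, 17 of them with a change of sign and no call, and 6 lost the call. Counted by result, 249 of 297 called gene results and 37 of 41 called list results kept their call in every alternative. The count of called genes stayed within 1.5 times its value except as follows. Requiring at least 1.5-fold gave 2411 genes for siOct4, 2731 for siCcnf+siNipp1, 2523 for siOct4 against siCcnf+siNipp1, 2322 for siOct4 against siRb1 and 2580 for siCcnf+siNipp1 against siRb1. An adjusted p under 0.01 gave 2180, 2575, 2279, 2107 and 2402 in this order and 144 for siRb1; both thresholds remove genes by construction. For siRb1 a replicate block gave 1162, arrayWeights 1035 and leaving out the 4 arrays numbered 1 gave 241. Same-direction calls with siRb1 were 598 (siOct4) and 623 (siCcnf+siNipp1) with the block, and 131 and 152 without the arrays numbered 1; the cause was not tested beyond fewer arrays. Camera with an estimated correlation called 0, 0 and 0 lists, and fry 3 for siRb1. The second POU5F1 probe reversed the fall with siOct4 (0.27); the cause was not settled. Leaving out 1 array gave 165 (control replicate 3) to 347 (control replicate 1) genes for siRb1, and 93 to 268 and 102 to 280 same-direction calls of siRb1 with siOct4 and siCcnf+siNipp1. It gave 2795 to 3652 genes for siOct4 and 3226 to 4039 for siCcnf+siNipp1, 15 to 17, 18 to 21 and 6 to 7 lists, and log2 fold changes of -5.55 to -5.11 for POU5F1, -1.86 to -1.37 for CCNF and -2.11 to -1.72 for RB1. Background limits POU5F1 and RB1, which were undetected after their siRNA and whose fitted values (-5.27 and -1.89) depend on its removal: they were -3.19 and -0.80 without background correction and -3.32 and -0.88 with the deposited normalized values. These falls are smaller than the bounds of 15.9- and 2.22-fold given for POU5F1 and RB1, which rest on the same removal of background. The mean of the POU5F1 probes gave -2.50. POU5F1 has no value with detection on all 12 arrays, and the slide block was not run.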

Other observations

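The gene lists tested here were chosen after their leading genes were seen, and the tests of the lists were set before their results; the test on CCNF was chosen after its result was seen. No gene of these lists is in the 33 lists fixed earlier, the leading genes themselves were left out of the lists, and adjusted p covers 9 tests.

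Camera called an antigen presentation list higher in all 3 knockdowns at the preset correlation and in none with an estimated one. A list of 34 genes was drawn up after BTN3A2 and MR1 were seen to rise with siCcnf+siNipp1, and 24 were measured. With siCcnf+siNipp1 16 rose and 1 fell, ULBP2 (-0.82), with a median of 0.93 and a camera adjusted p of 3.61e-06 (0.23 with an estimated correlation). With siOct4 19 rose and 0 fell (median 1.25, adjusted p = 1.36e-09; 0.219 with an estimated correlation), and with siRb1 5 rose and 0 fell (median 0.49, adjusted p = 8.55e-08; 0.219 with an estimated correlation). TAP1, a subunit of the peptide transporter of class I presentation, rose by 2.44, 2.25 and 1.34 with siOct4, siCcnf+siNipp1 and siRb1, and TAPBP, which loads peptides, by 2.16, 1.78 and 0.88. HLA-B rose by 2.92 and 2.18 and HLA-F by 2.50 and 1.90 with siOct4 and siCcnf+siNipp1, though probes for class I genes may read several of them. These genes are induced by interferon, so their rise is not independent of the interferon list.

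An oxidative stress response list was drawn up after AKR1C3 and GPX2 were seen. AKR1C3 was among the largest rises with siCcnf+siNipp1, while GPX2 fell with siOct4, siCcnf+siNipp1 and siRb1 (-1.27, -1.70 and -1.87). With siCcnf+siNipp1, of 23 measured genes 10 rose and 1 fell, PGD (-0.70), with a median of 0.38 and a camera adjusted p of 0.0013 (0.23 with an estimated correlation). The largest rises were AKR1C2 (2.55) and AKR1C4 (2.07), of the same gene family as AKR1C3. Whether their probes tell these genes apart was not tested. With siOct4 6 rose and 0 fell (adjusted p = 0.0253; 0.373 with an estimated correlation), and with siRb1 1 rose (adjusted p = 0.986). NQO1, a quinone reductase, rose by 2.19, 1.16 and 1.16 with siOct4, siCcnf+siNipp1 and siRb1, and HMOX1, heme oxygenase 1, by 2.41 with siOct4. The idea that AKR1C3 rises as part of a wider stress response may be kept as a hypothesis for siCcnf+siNipp1, though GPX2 went the other way.

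FLG, PI3 and SLPI rose with siOct4, and a wider epidermal differentiation program was tested as a hypothesis. Of 63 genes 15 were measured; MAL (1.55), KRT15 (at least 2.54-fold higher), CNFN (0.60) and DMKN (0.39) rose and DSC2 (-0.84) fell, with a median of 0.12 and a camera adjusted p of 0.303 (0.447 with an estimated correlation). The adjusted p alone had been set to count against the program. That bound was wrong, since a p over the threshold does not show absence and only 15 genes were measured. The hypothesis stays open without support from camera. Fry gave an adjusted p of 0.0228, but it does not compare the list with other genes. With siOct4 it called 24 of the 30 fixed lists tested, so it cannot decide here. With siCcnf+siNipp1 0 of the 15 rose by the limma test and 4 fell, KRT13, CNFN, DMKN and TGM1 (camera adjusted p = 0.209, fry adjusted p = 0.0053). With siRb1 1 rose, MAL (1.215, limma adjusted p = 0.00687), and the list did not pass (camera adjusted p = 0.943).

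CCNF, the target of another siRNA here, fell with siOct4 by -0.96, and it was asked whether it fell further than G2/M genes as a group. Of the 33 genes of that list 36.4% lay above CCNF and 21 fell further, so its fall was within the range of the list.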
